A study of Mus musculus with 6 samples.

How the data were processed

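Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MC3T3, a mouse pre-osteoblast cell line. Per the labels, cells were fixed in formaldehyde and sonicated, and 6 libraries were made: PRDM5 with 2 custom polyclonal antibodies (ab1 and ab2), an unrelated IgG, H3K4me3, H3K9 methylation and transcribing RNA polymerase II (Pol II). Peak lists of 5 of these were used, and the IgG library itself was not analysed here. The H3K9 library is called H3K9Me1 in its own labels and H3K9Me3 in the series' design text and file name, and is written as H3K9 methylation throughout. Each library stands alone. There are no replicates, so the p-values below describe how these lists lie on the genome and not the spread between cultures.

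The authors' peak lists were taken as deposited. The PRDM5 lists were called by MACS against a control library named s5, per the file headers, and the design text says that the IgG served as background. Each deposited PRDM5 peak carries a MACS score, whose scale is not given in the sources used here. Scores start at 50 and few pass 3100 (40 ab1 and 74 ab2 peaks are at or above it), many at that very value, so the strongest peaks are tied. The plan written before the data were examined had assumed islands of 1 caller for all lists. The scores are the authors' own and were used only to rank peaks within a list. Alignment with Bowtie, island calling with SICER and the genome build mm9 are named in the submitters' processing notes. The deposited H3K4me3, H3K9 methylation and Pol II lists give a whole number per island, taken here as the count of reads in the island, as SICER writes it; neither the labels nor the files say so. H3K4me3 islands lie on a grid of 200 bp, and H3K9 methylation and Pol II islands on grids of 600 bp. Versions, window settings, thresholds and the treatment of duplicate reads are not given in the sources used here. Because the callers and settings differ, numbers and lengths of islands are not comparable between PRDM5 and the other lists. Library depth is unknown: reads outside islands are not in the lists, and no depth-dependent limit is given.

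Coordinates are those of the lists on mm9, written from base 1. All 5 lists reach beyond the last gene of chromosome 1 in the only gene table at hand, which is on the GRCm38 assembly. That table was used for gene symbols, the number of protein-coding genes per chromosome and gene order, and no positions were converted between builds. Peaks were therefore not assigned to genes. The comparisons by gene body, by gene class and by gene list that were set out before the data were examined were not analysed here, and regions are named by position.

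An overlap needed 1 bp. Common PRDM5 regions were made by merging ab1 and ab2 peaks that overlapped and keeping merged regions that held a peak of each. For 8 overlaps, set out before the data were examined, the observed share was compared with 1000 circular shifts of the list within each chromosome, with the largest end in any list as the chromosome's length. The p is two-sided, and 0.001 is the smallest these shifts can give. Adjustment was by Benjamini-Hochberg over the 8 overlaps. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which treat islands as independent and cover counting error only. Peaks seen with both antibodies were compared with those seen with 1 by Fisher's exact test, two-sided, adjusted over 6 comparisons. Of these, the 2 on Pol II were set out before the data were examined. The regions named were the 15 common regions with the best mean rank of the scores in both lists. The comparisons of shared with single-antibody peaks on H3K4me3 and H3K9 methylation, the placement of regions inside Pol II islands, the clusters (at least 5 common regions with gaps under 20 kb), the Pol II deciles, the score quintiles and the chromosome densities were chosen after seeing the data. Clusters were compared with 1000 random placements, score trends were tested with 10000 permutations and relations across chromosomes with 100000. Alternatives covered the overlap rule, the score threshold, shifts limited to between 100 kb and 1 Mb, joining of islands under 1 kb apart, removal of islands met by all other lists, and autosomes only.

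The shift test was checked on simulated data, with 100 shifts per list. Of 100 lists of 3284 peaks placed independently and evenly over the chromosomes, 3 had p under 0.05 against the Pol II islands. The check does not cover lists that cluster or follow gene density, as the PRDM5 lists do. When 200 peaks were planted in Pol II islands, all 20 simulated lists were called, and the estimated number of planted peaks was 191 ± 12.5 (SD over those 20 lists). Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.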

Results

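PRDM5, a zinc finger protein of the PR-domain family, was profiled by ChIP-seq in MC3T3 cells together with Pol II, H3K4me3, a mark of active promoters, and H3K9 methylation. The series asks how PRDM5 relates to Pol II and to collagen gene transcription. The PRDM5 lists held 3284 peaks with ab1 and 5341 peaks with ab2. The ab1 peaks had a median length of 180 bp (interquartile range 130 to 258 bp) and covered 0.758 Mb. The ab2 peaks had a median length of 418 bp (344 to 514 bp) and covered 2.51 Mb. Pol II gave 29638 islands with a median length of 4800 bp (3000 to 9000 bp), which covered 249 Mb, or 9.44% of the genome span. H3K4me3 gave 18275 islands with a median of 2000 bp over 41.1 Mb. H3K9 methylation gave 21170 islands with a median of 3600 bp over 93.5 Mb. The reads listed inside islands came to 12877501 for Pol II, 14859567 for H3K4me3 and 1635660 for H3K9 methylation. Median read density was 273 reads per kb in H3K4me3 islands, 37.2 in Pol II islands and 14.3 in H3K9 methylation islands.

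The first question was whether both PRDM5 antibodies found the same sites. Of the ab1 peaks, 2307 (70.2%, 95% interval 68.7 to 71.8%) overlapped an ab2 peak, against 0.17% ± 0.076 (SD of 1000 shifts) after shifting. Of the ab2 peaks, 2156 (40.4%, 39.0 to 41.7%) overlapped an ab1 peak, against 0.10% ± 0.044 after shifting. Both shares lay beyond every shift (permutation p = 0.001, the smallest that 1000 shifts can give, adjusted p = 0.0016). Both lists were called against the same control library, so part of this overlap may come from that control. Merging gave 2156 common PRDM5 regions with a median length of 508 bp, 1.26 Mb in all. Across these regions the scores of the antibodies ranked alike (Spearman rho = 0.84, permutation p = 0.0001, the smallest that 10000 permutations can give; regions are not independent replicates). Peaks found with both antibodies had a median score of 116 with ab1 and 242 with ab2. Peaks found with 1 antibody had medians of 56.5 with ab1 and 70.4 with ab2.

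Common PRDM5 regions lay mainly on DNA covered by Pol II. Of the 2156 regions, 1439 (66.7%, 64.7 to 68.7%) overlapped a Pol II island, against 11.9% ± 1.12 after shifting, a 5.63-fold excess (permutation p = 0.001, adjusted p = 0.0016). When shifts were limited to between 100 kb and 1 Mb, which keeps regions in their own neighbourhood, the shifted share was 20.7% ± 1.18 and the excess was 3.22-fold (permutation p = 0.001). Without the islands met by all other lists, 55.0% of the common regions overlapped Pol II, against 11.3% after shifting. That setting takes out 196 Pol II islands, each of which meets both PRDM5 lists by construction.

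H3K4me3 overlapped fewer PRDM5 regions than Pol II did. A total of 867 common regions (40.2%, 38.1 to 42.3%) overlapped an H3K4me3 island, against 2.18% ± 0.356 after shifting, an 18.4-fold excess (permutation p = 0.001, adjusted p = 0.0016). With the limited shifts the excess was 10.5-fold. Most H3K4me3-positive regions also met Pol II: 830 regions (38.5%, 36.4 to 40.6%) met both and 37 (1.72%, 1.21 to 2.36%) met H3K4me3 without Pol II. Pol II without H3K4me3 was found at 609 regions (28.2%, 26.4 to 30.2%), and 680 regions (31.5%, 29.6 to 33.5%) met neither. The median ab2 score was 246 in regions with both, 275 in those with Pol II without H3K4me3, 284 in the 37 with H3K4me3 without Pol II and 207 in those with neither. Of the common regions centred inside a Pol II island, 1414 were shorter than that island, and 827 of these (58.5%) overlapped H3K4me3. Random placement inside the same Pol II islands gave 33.8% ± 0.91, so PRDM5 regions met H3K4me3 1.73 times as often (permutation p = 0.001).

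**Figure D1:**
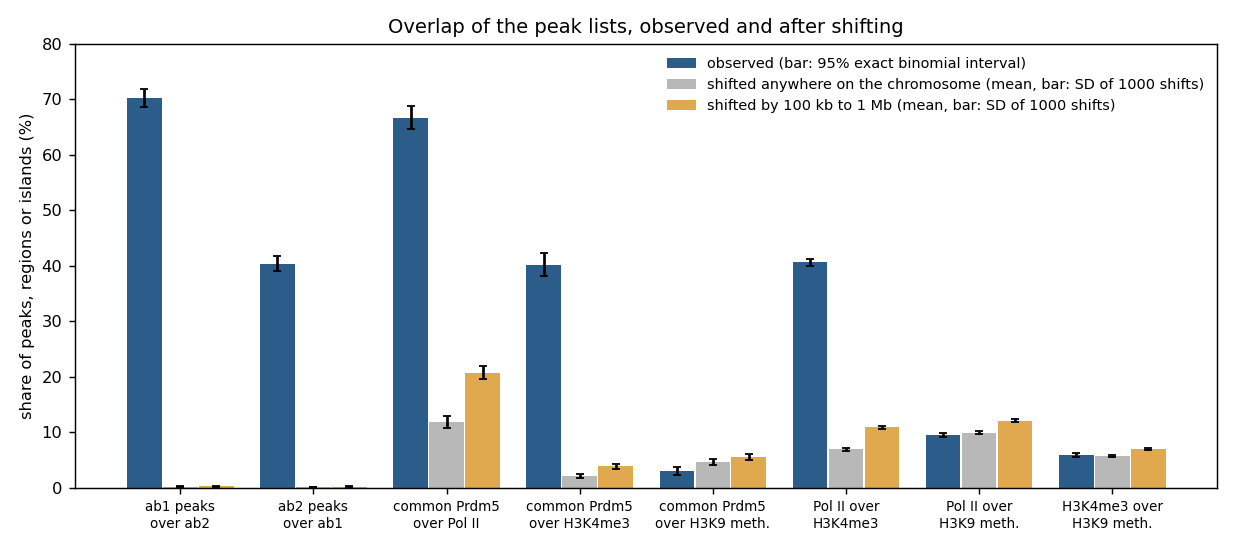
Share of peaks, regions or islands (%) that overlap another list, for the 8 overlaps. Blue bars are observed shares with 95% exact binomial intervals; grey and orange bars are means ± SD of 1000 shifts anywhere on the chromosome and of 100 kb to 1 Mb. Common PRDM5 regions overlapped Pol II in 66.7% and H3K4me3 in 40.2%, far above both shifted levels, and H3K9 methylation in 3.01%, below both.

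H3K9 methylation islands were rare at PRDM5 sites, as they were at shifted positions, and somewhat rarer than there. A total of 65 common regions (3.01%, 2.33 to 3.83%) overlapped an H3K9 methylation island, against 4.57% ± 0.539 after shifting, a ratio of 0.66 (permutation p = 0.00599, adjusted p = 0.00799). With the limited shifts the ratio was 0.546 (permutation p = 0.001). The H3K9 methylation islands covered 3.54% of the genome span, at a median of 14.3 reads per kb. A region without such an island may therefore still carry the mark. The overlaps between the other lists serve as a scale. Of the Pol II islands, 12038 (40.6%, 40.1 to 41.2%) overlapped H3K4me3, 5.89-fold above shifted positions (permutation p = 0.001). Pol II islands overlapped H3K9 methylation in 9.44%, against 9.95% ± 0.297 after shifting, a difference that did not pass the test (permutation p = 0.0739, adjusted p = 0.0845). With the limited shifts the expected share was 12.1% ± 0.223, and the observed share was below it (permutation p = 0.001). H3K4me3 islands overlapped H3K9 methylation in 5.90%, against 5.72% ± 0.246 (permutation p = 0.459). With the limited shifts the expected share was 6.97% ± 0.198, and the direction turned to fewer overlaps than expected (permutation p = 0.001).

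Peaks found with ab1 alone were placed differently from those found with both antibodies. Of the 977 ab1-only peaks, 36.6% (33.6 to 39.8%) overlapped Pol II, against 66.8% (64.9 to 68.8%) of the ab1 peaks shared with ab2 (Fisher's exact test, p = 2.02e-57, adjusted p = 1.21e-56). H3K4me3 was met by 22.7% of the ab1-only and 39.2% of the shared ab1 peaks (Fisher's exact test, p = 2.20e-20, adjusted p = 6.60e-20). H3K9 methylation went the other way, at 8.90% of ab1-only and 2.95% of shared ab1 peaks (Fisher's exact test, p = 3.57e-12, adjusted p = 7.14e-12). The 3185 ab2-only peaks met Pol II in 66.6% (64.9 to 68.2%), against 66.7% of the shared ab2 peaks, a difference of 0.182 percentage points (Fisher's exact test, p = 0.906). They met H3K4me3 more often than the shared ab2 peaks, at 45.3% against 40.2% (Fisher's exact test, p = 0.000227, adjusted p = 0.000341). H3K9 methylation was met by 3.92% of ab2-only and 3.01% of shared ab2 peaks, a difference that did not pass the test (Fisher's exact test, p = 0.0834). For ab1 the Pol II difference was 30.2 percentage points in the full lists. With every list limited to values at or above its median, which left 177 ab1-only peaks, it was 6.67 points and did not pass the test (Fisher's exact test, p = 0.0906). In the same setting the H3K4me3 difference turned round, with 45.8% of ab1-only and 30.2% of shared ab1 peaks on H3K4me3 (Fisher's exact test, p = 5.28e-05). This setting shortens the Pol II and H3K4me3 lists as well as the PRDM5 lists.

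Over all peaks of each list, the overlap with Pol II was higher in the highest than in the lowest score quintile. In the lowest score quintile of ab1, 41.6% (37.8 to 45.4%) of peaks met Pol II, and in the highest 72.0% (68.4 to 75.4%) did. For ab2 the shares were 59.9% (56.9 to 62.8%) and 71.1% (68.2 to 73.8%). The rank correlation of score and Pol II overlap across peaks, which are not independent replicates, was 0.216 for ab1 and 0.0734 for ab2 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give). The share of ab1 peaks shared with ab2 went from 32.4% to 98.2% between those quintiles, and that of ab2 peaks shared with ab1 from 6.74% to 97.8%. Among shared ab1 peaks alone, Pol II overlap did not rise steadily over the quintiles (65.7%, 69.0%, 63.3%, 63.7% and 71.9%). Among ab1-only peaks it was 30.0%, 35.2%, 44.7%, 81.0% and 75%, on 444, 338, 141, 42 and 12 peaks. The rise over all ab1 peaks thus partly reflects the falling number of ab1-only peaks. H3K4me3 overlap rose for ab1 from 22.5% to 40.9%. For ab2 it was 39.9% (37.0 to 43.0%), 42.4%, 46.9% (43.9 to 49.95%), 45.0% and 41.9% (38.97 to 44.97%) from the lowest to the highest quintile, highest in the middle, and a steady trend with score did not pass the test (rank correlation 0.0224, permutation p = 0.104). H3K9 methylation overlap fell with score, from 6.85% to 2.44% for ab1 and from 4.12% to 2.90% for ab2 (permutation p = 0.0001 and 0.0343, adjusted over 8 trends p = 0.000133 and 0.0392).

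**Figure D2:**
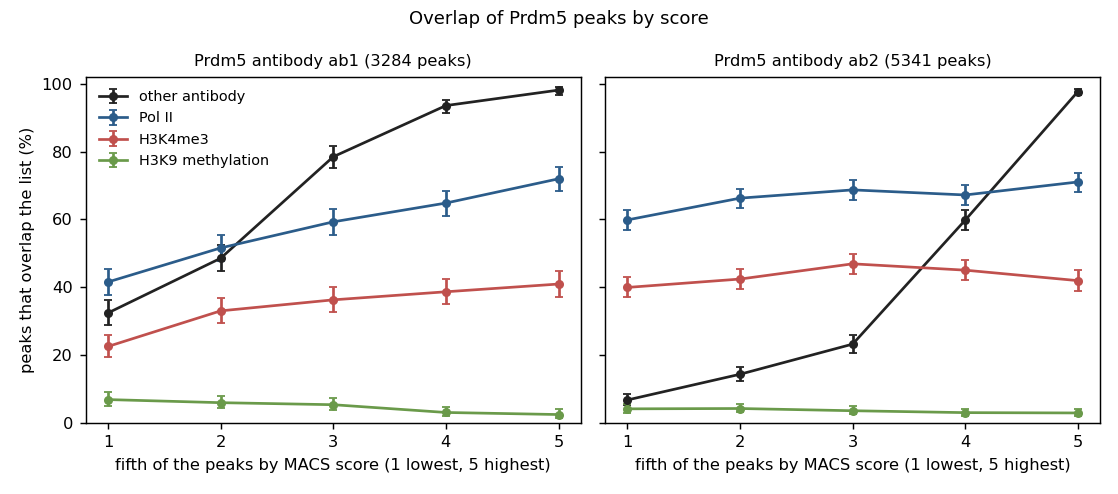
Share of PRDM5 peaks (%) that overlap the other antibody's list, Pol II, H3K4me3 and H3K9 methylation, by quintile of the MACS score within each list (1 lowest, 5 highest); bars are 95% exact binomial intervals. Overlap with Pol II goes from 41.6% to 72.0% for ab1 and from 59.9% to 71.1% for ab2.

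Of the 15 common regions with the best mean rank, 10 lay in clusters, 13 met Pol II, 6 met H3K4me3 and 1 met H3K9 methylation. The longest was a region of 14926 bp on chromosome 11 (94798125 to 94813050), with a score of 3100 in both lists. It met Pol II, H3K4me3 and H3K9 methylation. On chromosome 6, 6 of the 15 regions lay between 4459423 and 4488542; all were within 1 Pol II island, and 2 of them met H3K4me3. A region of 3704 bp on chromosome 2 (27870853 to 27874556) met Pol II only. On chromosome 1, regions at 45381951 to 45383102 (score 3223 with ab1, the highest of that list) and 45396517 to 45398471 lay close together. The first of these met none of the other lists and the second met Pol II only. Outside clusters, regions on chromosome 7 (108449846 to 108451026 and 138702998 to 138703883) and chromosome 15 (66723396 to 66725445) met Pol II and H3K4me3. A region on chromosome 5 (125519285 to 125521314) met Pol II only, and one on chromosome 1 (24323238 to 24325303) met none. Because the score stops near 3100, 36 common regions had at least that score in both lists. Ties in rank were ordered by length, so the choice favours long regions and does not order the tied ones by strength. How many of the 15 lay on chromosome 6 or in clusters depends on that rule.

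Common PRDM5 regions formed 16 clusters of at least 5 regions with gaps under 20 kb, a definition chosen after seeing the data. When regions under 1 kb apart were first joined into 1, 8 such clusters were found. The clusters held 156 regions, 7.24% of the total. Random placement of the regions as points on the same chromosomes gave 0.001 clusters on average and at most 1, and random placement that kept each chromosome's number of regions inside Pol II gave 0.069 on average and at most 2 (permutation p = 0.001 for each, 1000 placements). The first, on chromosome 1 (45436794 to 45492061), held 22 regions over 55.3 kb. The next, on chromosome 2 (27813803 to 27876421), held 21 regions within a single Pol II island of 170 kb. A neighbouring cluster on chromosome 1 (45378315 to 45403037) held 16 regions. On chromosome 8 (11210640 to 11246048) there were 12 regions, and on chromosome 6 (4455549 to 4490061) 10 regions covered 75.2% of the cluster. The cluster on chromosome 11 (94776947 to 94819790) had 6 regions, which covered 52.8% of it. Clusters of 10 regions lay on chromosome 15 (97808175 to 97829333) and at 2 places on chromosome 4 (62914331 to 62980854 and 129734787 to 129778318). Of the 16 clusters, 13 met Pol II, 4 held an H3K4me3 island and 2 an H3K9 methylation island. The clusters on chromosomes 1 (24228183 to 24246400), 17 (34188905 to 34201149) and 3 (113860899 to 113897259) met none of these. Pol II density differed widely between clusters: the densest Pol II island had 534 reads per kb in the chromosome 11 cluster, 365 in the chromosome 6 cluster, 86.2 in the chromosome 2 cluster and 33.8 in the chromosome 8 cluster, against a median of 37.2 over all Pol II islands. No gene is assigned to these positions, since no mm9 gene annotation was used.

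**Figure D3:**
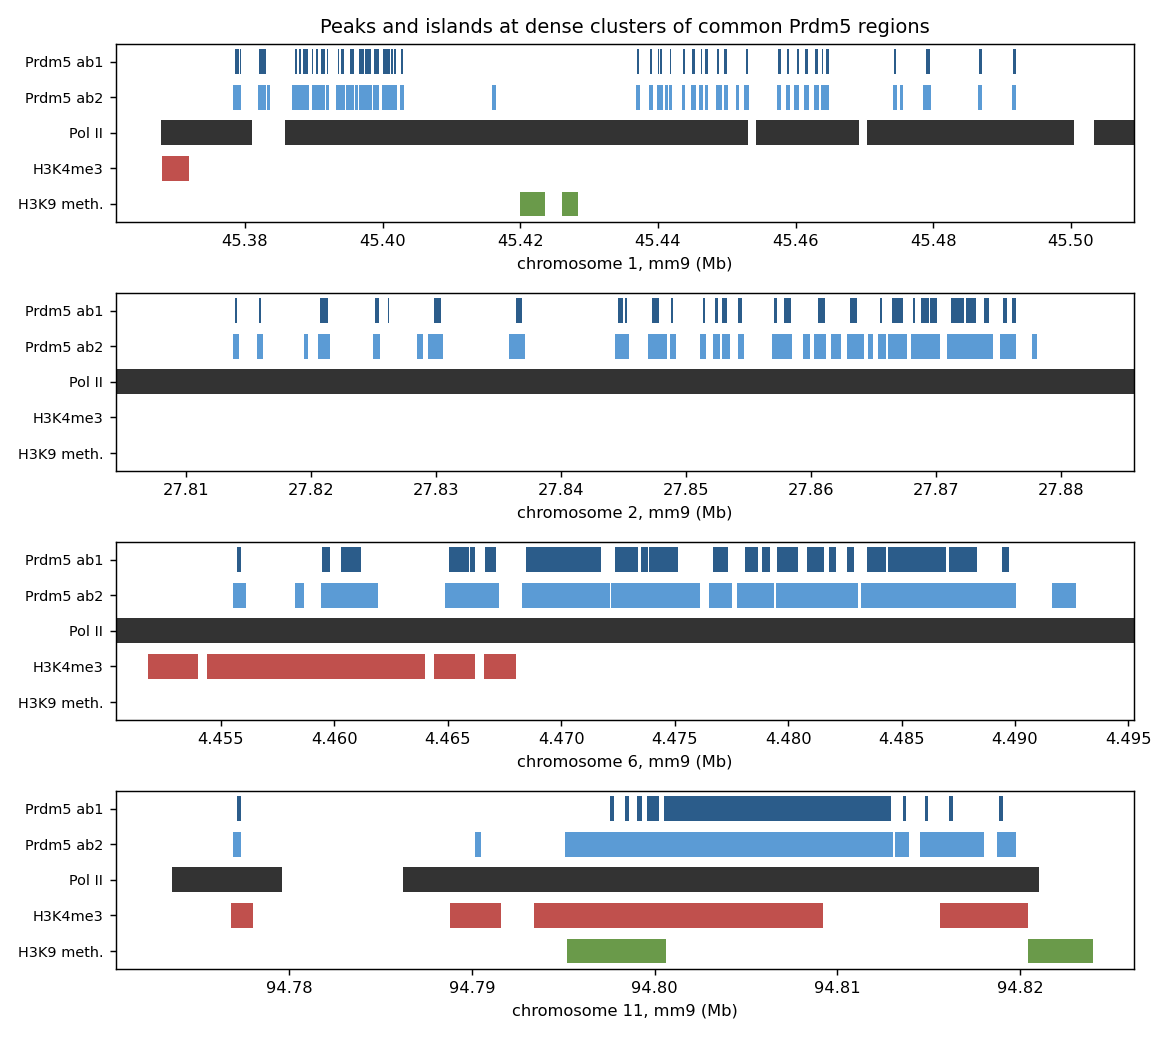
Positions of PRDM5 peaks and of Pol II, H3K4me3 and H3K9 methylation islands (filled bars) around 5 clusters on chromosomes 1, 2, 6 and 11; x axes are mm9 positions in Mb, to scale within each panel. Pol II covers 100% of the clusters on chromosomes 2 and 6, 95.7% and 80.6% of those on chromosome 1 and 84.6% of that on chromosome 11. H3K4me3 covers 33.8% of the chromosome 6 cluster, 55.7% of the chromosome 11 cluster and none of the others shown.

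Seen from Pol II, few islands carried PRDM5. Common PRDM5 regions were found on 1198 of the 29638 Pol II islands. These were longer, with a median of 12 kb (interquartile range 4.8 to 29.4 kb) against 4.8 kb (3 to 8.4 kb) for the 28440 others. They were also denser in reads, with a median of 58.0 reads per kb (43.7 to 84.3) against 36.7 (28.7 to 53.8), and 79.6% of them held H3K4me3 against 39.0%. Among Pol II islands of at least 3 kb, those with PRDM5 made up 0.491% (0.245 to 0.877%) of the decile with the lowest read density and 14.4% (13.0 to 15.9%) of the decile with the highest. Lengths were not matched in this comparison.

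Chromosomes rich in genes tended to hold more PRDM5 peaks, with chromosome 7 as an exception: it had the most protein-coding genes per Mb (13.3), but 0.780 ab1 peaks and 1.73 ab2 peaks per Mb. With ab1 there were 2.59 peaks per Mb on chromosome 17 and 2.53 on chromosome 19, against 0.312 on the X chromosome. With ab2 there were 3.99 on chromosome 19, 3.90 on chromosome 11 and 0.432 on the X. Across the autosomes and the X (20 chromosomes, which are not replicates), ab1 peaks per Mb went with protein-coding genes per Mb (Pearson's r = 0.590, permutation p = 0.00646; Spearman's rho = 0.565, p = 0.0109). For ab2 r was 0.687 (permutation p = 0.00116) and rho 0.677 (p = 0.0014). For Pol II r was 0.724 (permutation p = 0.00016) and rho 0.802 (p = 4e-05). For H3K4me3 r was 0.815 (permutation p = 3e-05) and rho 0.893 (p = 1e-05, the smallest that 100000 permutations can give). Over 6 relations computed, the adjusted p-values for ab1 were 0.00969 for r and 0.0164 for rho, and those for ab2 were 0.00232 and 0.0028. For Pol II they were 0.00048 and 0.00012, and for H3K4me3 0.00018 and 6e-05. Without chromosomes 7 and 11, the 2 chromosomes farthest from the median gene density, r was 0.789 for ab1, 0.806 for ab2, 0.763 for Pol II and 0.851 for H3K4me3. Chromosome 7 is the exception named above, so a higher r without it does not strengthen the relation. For H3K9 methylation islands per Mb the relation to gene density did not pass the test (r = 0.423, permutation p = 0.0615, adjusted p = 0.0738; rho = 0.328, permutation p = 0.158, adjusted p = 0.19), and without the same 2 chromosomes r was 0.572 and rho 0.418. They ranged from 1.95 per Mb on the X to 15.1 on chromosome 10 and 18.6 on chromosome 17.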

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

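The tests below were set out after the difference between the antibodies was seen and before their own results were. The gap between peaks found with both antibodies and peaks found with 1 antibody differed between ab1 and ab2. For Pol II overlap the odds ratio of shared against single-antibody peaks was 3.49 for ab1 and 1.01 for ab2, a ratio of 3.46 (95% Wald interval 2.85 to 4.199). The ratio was 2.70 (2.20 to 3.31) for H3K4me3 and 0.408 (0.262 to 0.637) for H3K9 methylation. These intervals treat both odds ratios, and all peaks, as independent. The shared peaks enter both odds ratios, which by itself makes the intervals too wide. Peaks are not independent, which by itself makes them too narrow. The net direction was not tested, so the intervals are only a rough guide.

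Single-antibody ab1 peaks met Pol II 29.9 percentage points less often than single-antibody ab2 peaks (95% interval 26.5 to 33.4). Within quintiles of the ab1 score, shared ab1 peaks still had a Mantel-Haenszel odds ratio of 2.86 (2.37 to 3.43) for Pol II overlap against ab1-only peaks. That ratio is an average over unlike quintiles. In the lowest, 65.7% of shared and 30.0% of ab1-only peaks met Pol II. In the 2 upper ones the 42 and 12 ab1-only peaks met Pol II in 81.0% and 75% of cases, against 63.7% and 71.9% of shared peaks. No ab2-only peak enters the ratio. It therefore cannot decide whether lower scores explain the gap between ab1-only and ab2-only peaks. Shorter ab1 peaks and segments rich in H3K9 methylation are argued against, since the difference was 30.0 points (26.5 to 33.4) with all peaks set to 500 bp and 30.6 points (25.95 to 35.2) outside the richest quartile of 5 Mb bins. A larger share of unspecific calls among low-scoring ab1 peaks, and antibodies that see different forms of PRDM5, remain open and were not tested.

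Pol II islands on the mitochondrial chromosome, which the comparisons of the report do not describe, held 1094 reads in 2 islands, or 91.2 reads per kb, above 93.3% of all Pol II islands. This density was not adjusted here for the number of DNA copies or for a control library, so it does not show that Pol II binds there.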

How the results depend on the processing

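The results for H3K4me3 and H3K9 methylation in shared against single-antibody peaks, for clusters and for placement inside Pol II islands, and their alternatives, were chosen after seeing the data. Of 54 values under the alternatives set out beforehand for 10 results, 44 kept their direction and side of the 0.05 threshold. Over them the share of common PRDM5 regions on Pol II ranged from 55.0% to 67.0%, that on H3K4me3 from 30.8% to 41.4% and that on H3K9 methylation from 1.71% to 3.07%. Pol II islands over H3K9 methylation passed the threshold, below the shifted level, with lists limited to values at or above their median (7.53%) and with limited shifts (9.44%). H3K4me3 islands over H3K9 methylation turned to fewer than expected under the same settings (2.29% and 5.90%). The Pol II difference of shared minus single-antibody ab1 peaks was 6.67 points with limited lists and did not pass the threshold, and the H3K4me3 difference turned to -15.6 points. For ab2 the Pol II difference, which did not pass the threshold in the full lists, was -0.379 points with 50% of the shorter interval covered and -2.93 with limited lists. The ab2 H3K9 methylation difference was -1.004 points with the stricter overlap (Fisher's exact test, p = 0.0473, but 0.0568 when adjusted over 6 comparisons). Leaving out islands met by all other lists lowers several shares by construction, since each island taken out meets both antibodies and every mark, and its values are no test of these results: 8.83% for Pol II over H3K9 methylation, 5.68% for H3K4me3 over H3K9 methylation, and for ab2 -6.45 points for Pol II and -1.94 points for H3K9 methylation. Clusters numbered 14 and 24 with gaps of 10 and 50 kb, and 8 with regions under 1 kb apart joined, which lowers the number of regions by construction. For the other changes the cause was not tested. No paired analysis was possible because each group has 1 library. The alternatives for gene-level results were not run, since no mm9 annotation was used, and depth limits were not set, because reads outside islands are not in the lists.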

Other observations

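The tests of weak H3K4me3 islands in the chromosome 12 segment and of collagen genes were chosen after the result was seen, and that segment was itself picked for its many islands. The largest H3K9 methylation islands by reads lay on chromosome 9 (2999401 to 3076800, 99029 reads, 6.05% of all reads in H3K9 methylation islands), chromosome 2 (98501401 to 98508000, 19260 reads) and chromosome 11 (3018601 to 3100200, 11575 reads). The longest ab1 peak, 24.8 kb on chromosome 9 (3013592 to 3038430), lay inside the first of them and met no ab2 peak and no Pol II island. The chromosome 9 island held 3 ab1 peaks, the chromosome 2 island 2 and the chromosome 11 island none, and no ab2 peak lay in any of them. No region was removed for unusual read density, and the IgG library was not analysed. Reads that gathered in these islands for reasons other than the mark can therefore not be told apart. The longest Pol II island spanned 322 kb on chromosome 15 (63901801 to 64224000) and held 1 ab1 and 2 ab2 peaks.

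H3K9 methylation islands were spread unevenly, and chromosome 12 held 385 of its 970 islands (39.7%) between 15 and 25 Mb, or 192.5 per 5 Mb bin against a median of 22 in its other bins. A high number of active promoters is argued against for this segment. Of the chromosome's strong H3K4me3 islands (at or above the median read density), 4.95% lay there, a ratio of shares of 8.02 (95% interval 4.87 to 13.2). Picking the segment for its H3K9 methylation islands raises that ratio. Genes without a strong H3K4me3 island are not counted, so gene content itself was not tested. A candidate explanation is more copies of this DNA in the cell line, since weak H3K4me3 islands outside Pol II were also frequent there, at 5.51 times the share of strong ones (3.11 to 9.77). Repeated sequence in the segment would give the same picture and was not tested, nor was a biological explanation. For whole chromosomes, H3K9 methylation islands per Mb were set against the ratio of weak to strong H3K4me3 islands. A positive rho with a permutation p under 0.05 had been set out beforehand as the sign of copy number. A rho that was not positive was to count against it, whatever its p. The rho was -0.253 over 20 chromosomes (permutation p = 0.281), and Pearson's r was -0.148 (permutation p = 0.534). Without the 2 chromosomes farthest from the median, r was -0.408. The predicted sign was not seen, and the rho lay on the side set out as against copy number. Since neither relation passed the test, copy number still cannot be told apart from other causes at this scale.

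High recovery of any ChIP over heavily transcribed DNA is argued against as the whole cause of the dense PRDM5 clusters, since 3 of the 16 met no Pol II island. For the other clusters it stays open. Of the 225 Pol II islands of at least 3 kb in the top 1% by read density, 24.4% (18.98 to 30.6%) held a common PRDM5 region. That share was above the 4.71% of all 22408 islands of at least 3 kb. It counts islands with any common region, not clusters, and the IgG library was not analysed. It therefore cannot decide what part recovery played. Splitting of broad peaks by the caller could account for part of the count, since joining regions under 1 kb apart left 8 clusters. A hypothesis taken from the series title is that clusters mark collagen genes, which was examined only by chromosome. Of all 16 clusters, 13 lay on a chromosome with 1 of 11 fibrillar collagen genes, as did 4 of the 5 largest (57.8% of common regions do). Chromosome 8 carries no fibrillar collagen gene, so its cluster cannot mark a gene of that kind. That says nothing against collagen genes of other kinds. A wider list of 44 collagen genes had members on 15 chromosomes, and all 16 clusters lay on those. With the 44 collagen genes listed before the data were examined, the cluster chromosomes held 3.38 collagen genes on average against 2.37 ± 0.520 (SD of 10000 draws weighted by protein-coding genes, one-sided permutation p = 0.0322), but with neighbouring clusters counted as 1 locus the 15 loci gave 3.13 against 2.37 ± 0.537 (permutation p = 0.0913), and with each of their 10 chromosomes counted once the value was 2.90 against 2.35 ± 0.464 (permutation p = 0.151). Counts of genes on whole chromosomes cannot show whether a cluster lies in a collagen gene, and no cluster is placed in a gene. These values are therefore no test of the collagen hypothesis, which stays open here.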
